A study of Mus musculus with 3 samples.

How the data were processed

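RNA was measured in 3 libraries of F121-9 cells, a mouse embryonic stem cell line derived from a cross between the CAST and 129 strains. The labels describe long-read RNA sequencing, in which 1 read can span a transcript from end to end, and number the libraries as biological replicates 1, 2 and 3. They say nothing more about how the cultures were kept apart, so the p-values given here describe these libraries only. The p-values for gene and isoform counts measure departures from counting error. Those for paired differences compare values within each library. All libraries belong to 1 group, no second condition was analysed here, and no gene was tested for a difference between conditions.

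The authors deposited, per library, a table of whole-number read counts for each transcript model and an annotation file with the coordinates of those models. Per the file headers and the description supplied with each library, the models were placed on the mm10 genome with the GENCODE M21 annotation, and models outside that annotation carry TALON as their source. The sequencing platform, the aligner and the software versions are not given in the sources used here. The deposited counts are raw reads per model in 1 library, the lowest listed count is 1, and libraries were not pooled by the authors. Each model carries a class set by the authors: known, incomplete splice match (a contiguous part of a known chain of introns), in catalog (a chain not in the annotation built from known splice sites), not in catalog (a chain with at least 1 splice site outside the annotation), genomic, antisense or intergenic. No spike-in model was listed in any library (0 models), so the spike-in RNAs that the labels mention were not analysed here. All 715336 listed models had exons in the annotation files, with the exon number of the count table. Gene coordinates printed here are those of GENCODE M21, which matched the start, end and strand in the deposited annotation files for 38585 of 55536 genes. Coordinates of models outside the annotation are the authors' own.

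Counts of all classes were summed per annotated gene with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The libraries held 3242087, 2149966 and 1708941 reads for replicates 1, 2 and 3, of which 3037005, 2028166 and 1665123 fell in annotated genes. Levels are counts scaled to 1e+06 reads (CPM) on effective library sizes from TMM scaling in edgeR 4.0.16 (R 4.3.3), with factors of 0.995, 0.999 and 1.01. Log values are log2(CPM + 1). A count of 0 allows up to 3 counts, which is 0.988, 1.48 and 1.80 CPM in replicates 1, 2 and 3, or 0.446 CPM over all reads together. These limits and the intervals cover counting error only, because reads made by amplification without molecular tags are not independent molecules. For unannotated loci, levels are reads scaled to 1e+06 reads of the library (RPM).

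The spread between libraries was estimated as the common biological coefficient of variation with edgeR, using an intercept-only model and the genes kept by its expression filter with at least 10 counts in total. Pearson and Spearman correlations were taken across genes, which are not independent replicates. Each gene with an expected count of at least 5 in every library was tested for equal levels with a chi-square test of homogeneity against the effective library sizes (scipy 1.17.1), with Benjamini-Hochberg adjustment and a threshold of 0.05. This test compares libraries. Isoform usage was tested with a chi-square test of isoform by library counts in genes with at least 30 known-transcript reads in every library, after pooling isoforms with an expected count below 5. The number of genes with at least 2 known isoforms counted those at or above 10% of reads in every library. Models outside the annotation were matched between libraries by chromosome, strand and the exact chain of introns. The same chain could carry a different class in another library. Paired differences between classes and between length groups were tested with two-sided exact sign-flip permutation tests, whose smallest possible p with 3 libraries is 0.25.

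Gene lists were fixed before the data were examined: general, naive, and formative and primed pluripotency, the 2-cell-like state, primitive endoderm, mesoderm, neuroectoderm, trophoblast, feeder fibroblast, DNA methylation and oxidation, Polycomb, X inactivation centre, imprinted genes, cell cycle, housekeeping, p53 and stress response, long noncoding RNA, and isoform genes. The median of each list was placed among 10000 random lists of the same size drawn from the 22028 protein-coding genes of the annotation. Dux, Xite and Linx were not matched by symbol and are not analysed here. The named genes follow a rule fixed at the same time: list members (the highest and lowest mean CPM first), the 20 genes of highest mean CPM, the 10 genes of largest coefficient of variation among those with mean CPM of at least 50 that differed between libraries, the 10 genes with the largest range of an isoform share among those that differed in usage, the 10 most abundant in catalog or not in catalog models found in every library, and the most read known transcript of each isoform gene. Genes outside this rule are said to be chosen after their values were seen.

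Both chi-square tests and the dispersion estimate were tested on simulated counts drawn from the means and depths of these libraries. For the chi-square tests the counts held counting error only, Poisson for genes and multinomial for isoforms. These libraries spread more than that (common coefficient 0.171), so the calls in unchanged genes are not the rate of false calls in the data. Of genes changed in 1 library, the homogeneity test called 36% at 1.5-fold, 77.1% at 2-fold, 92% at 4-fold and 100% at 8-fold, and 6 of 11780 unchanged genes, with 11976 genes tested. The isoform test called 34.3%, 77.6% and 100% of genes with a share moved by 10, 20 and 40 percentage points, and 6 of 1685 unchanged genes, with 1885 genes tested. A simulated coefficient of 0.2 was estimated as 0.199 over 10309 genes.

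Near-identical copies were searched by aligning the most read known transcript of each tested or listed gene to all annotated transcripts with minimap2 2.31. A copy was another gene whose transcript aligned in the same orientation, at 95% identity or more over at least 200 bases and 80% of either transcript. Gene and copy may lie on different strands of the genome. A narrower definition, which required 80% of the gene's own transcript, was used first. It was widened after the alignments of Rplp0, Actg1, Ppia and a gene not reported here had been seen to give no copy, and both definitions are reported where a test rests on them. Counts of genes with copies are uncertain, since the sources used here do not say how reads that fit several genes were placed.

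Alternatives covered scaling (DESeq2 1.42.0 size factors, total counts), filters, pseudocounts, known transcripts only, reads thinned to the smallest library, splice-site tolerance, read minimums and leaving out each library in turn. Genes without a near-identical copy, and genes with at least 10 counts for the correlation, were added as alternatives after seeing the data. Plots were drawn with matplotlib 3.10.9. Alleles of the parental strains were not analysed here.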

Results

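Long-read RNA profiles were collected from 3 libraries of F121-9 mouse embryonic stem cells, all of 1 group. The question the design allows is which genes and transcript isoforms these cells express, and how far replicate libraries differ. Totals were 3242087, 2149966 and 1708941 reads, spread over 299238, 229871 and 186227 transcript models in replicates 1, 2 and 3. Values below are means ± SD over the libraries (n = 3) unless a single library is named.

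Regulators of pluripotency were among the well expressed genes of these cells. Nanog, a transcription factor of the naive state, was at 1057 ± 62.8 CPM (n = 3; chromosome 6, 122707489 to 122714633 on mm10), Klf5 at 874 ± 11.6 CPM and Zfp42 at 630.1 ± 45.6 CPM, while Dppa3 was the lowest naive gene at 23.7 ± 7.22 CPM. Of the general regulators, Sox2 was at 762 ± 32.9 CPM and Pou5f1, which encodes OCT4 (chromosome 17, 35506018 to 35510772), at 379.7 ± 129 CPM. Dppa5a led the general list at 3541 ± 1273 CPM, and Dnmt3l was its lowest member at 2.25 ± 0.628 CPM. The median of the naive list was 8.51 ± 0.05 in log2(CPM + 1), and that of the general list 7.66 ± 0.17, both above the 97.5th percentile of random lists. Pou5f1 was at 528 CPM in replicate 1 against 313 and 298 CPM in replicates 2 and 3, and Dppa5a was lowest in replicate 3 (2099 CPM). By the homogeneity test, 4 of 15 tested naive genes and 6 of 14 general genes differed between libraries, and 6 and 7 did when adjusted over the list alone. Dppa3 has an annotated near-identical copy, Dppa3-ps, with 177, 29 and 63 reads against 94, 47 and 28 on Dppa3, so its level is uncertain.

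Genes of formative and primed pluripotency, the states that follow the naive one, lay lower. Etv5 was the exception at 381 ± 30.5 CPM, followed by Dnmt3a at 58.0 ± 2.39 CPM, while Otx2 was at 10.03 ± 1.66 CPM. Fgf5 and Cer1 had 0 reads in every library, which allows up to 0.446 CPM. The list's median was 2.96 ± 0.11, at percentile 68.2 of random lists but at 14.7 of lists drawn from genes with at least 1 read, a background that leaves out unread genes while the list keeps them. In this list 1 of 10 tested genes, Etv5, differed between libraries, as did 1 adjusted over the list alone. Genes of the 2-cell-like state, a rare state of such cultures, were near the limit of detection. Zscan4e and Zscan4f were each at 3.82 CPM (SD 1.93 and 1.53), with reads shared uncertainly among near-identical Zscan4 genes, and Tcstv1 and Tcstv3 had 0 reads. The median of that list was 0.93 ± 0.21, and none of its 3 tested genes differed between libraries by either adjustment (0 genes).

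Markers of other cell types that such a culture could hold were mostly low. In the primitive endoderm list, the matrix gene Sparc was at 183 ± 5.44 CPM and Lama1 at 65.3 ± 7.38 CPM, whereas Sox17 was at 2.41 ± 0.597 CPM and Foxa2 had 0 reads. Among mesoderm genes, Cdx1 stood at 215.5 ± 23.4 CPM and T (Brachyury) at 9.93 ± 3.42 CPM, and Mesp1, Hand1, Msgn1 and Foxf1 had 0 reads. Among trophoblast genes, Tfap2c was at 236 ± 29.4 CPM, Krt8 at 13.6 ± 3.58 CPM and Cdx2 at 0.110 ± 0.191 CPM. Neuroectoderm genes reached 20.2 ± 4.04 CPM (Nes) and 18.3 ± 4.08 CPM (Tubb3), and Pax3, Olig2 and Dcx had 0 reads. The feeder fibroblast genes Col6a1 and Col1a1 were at 16.5 ± 2.95 and 2.75 ± 1.93 CPM, and Col3a1, Dcn, Acta2, Lum, Tagln and S100a4 had 0 reads. List medians were 2.65 ± 0.04 for primitive endoderm, 1.17 ± 0.20 for trophoblast, 1.04 ± 0.47 for mesoderm, 0.18 ± 0.17 for feeder fibroblast and 0.11 ± 0.19 for neuroectoderm, at percentiles 61.2, 31.5, 28.4, 8.13 and 7.5. Among lists of genes with at least 1 read these were 9.68, 0.57, 0.35, 0 and 0, and with known transcripts only 74.1, 50.8 and 38.6 for the first 3 and 23.5 for neuroectoderm. The feeder median was then 0, which ties with every random list of median 0, so no percentile is given. Over all genes tested, 1 of 8 primitive endoderm genes (Col4a2), 2 of 5 mesoderm genes (Cdx1 and Gsc) and 1 of 6 trophoblast genes (Tfap2c) differed between libraries. Adjusted over the list alone these counts were 0, 2 and 1, and among the 3 neuroectoderm and 4 feeder genes tested both counts were 0.

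Of the regulators of DNA methylation, Uhrf1, which recruits the maintenance methyltransferase, was at 888 ± 26.3 CPM, Dnmt1 at 350.5 ± 15.8 CPM, and the oxidases Tet2 and Tet1 at 87.9 ± 11.6 and 87.0 ± 20.2 CPM. Of the Polycomb genes, Suz12 was highest at 662 ± 90.1 CPM, Ezh2 was at 254 ± 4.35 CPM and Ring1 was lowest at 16.4 ± 3.39 CPM. The median of the DNA methylation list was 6.45 ± 0.15 (percentile 99.9) and that of the Polycomb list 7.88 ± 0.14, both above the 97.5th percentile. Tet1 was the 1 gene of 9 tested in the methylation list that differed between libraries, and 4 of 13 Polycomb genes did (Suz12, Mtf2, Jarid2 and Rnf2), with the same counts adjusted over the list alone (1 and 4).

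Of the genes around the X inactivation centre, the ubiquitin ligase gene Rlim was at 82.8 ± 7.78 CPM. Tsix was at 4.30 ± 2.30 CPM, and Xist, the RNA that coats the inactive X, had 0, 2 and 0 reads in replicates 1, 2 and 3. The list's median was 0.97 ± 0.05 (percentile 27.6, or 1.58 among genes with at least 1 read; with known transcripts only the median was 0 and tied with random lists of median 0), and 0 of 2 tested genes differed between libraries, also adjusted over the list alone. Imprinted genes covered a wide range. Impact was highest at 265 ± 20.1 CPM, Snrpn was at 189.7 ± 12.0 CPM and Meg3 at 85.02 ± 22.0 CPM, while H19 had 1, 0 and 0 reads and Igf2 had 0 reads. The median of the imprinted list was 3.80 ± 0.04 (percentile 86.8, or 32.5 among genes with at least 1 read), and Meg3 was the 1 gene of 16 tested that differed between libraries, by either adjustment (1 adjusted over the list alone).

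Cell cycle genes were abundant. The replication licensing gene Mcm2 was at 1327 ± 157 CPM, Ccnb1 at 727 ± 49.9 CPM and Ccnd3 at 859 ± 19.3 CPM, whereas Ccnd2 was at 0.363 ± 0.319 CPM and Cdkn2a at 0.275 ± 0.252 CPM. In the p53 and stress list, Hspa5 led at 744 ± 51.6 CPM, Trp53 was at 382.5 ± 3.84 CPM, and the heat-shock gene Hspa1a was lowest at 0.714 ± 0.742 CPM. Medians were 7.61 ± 0.11 for cell cycle and 7.11 ± 0.18 for p53 and stress genes, both above the 97.5th percentile. In the cell cycle list 6 of 12 tested genes differed between libraries (7 adjusted over the list alone), and in the p53 and stress list 4 of 13 did (7 adjusted over the list alone). Of the long noncoding RNAs, Gas5 was highest at 131 ± 46.4 CPM and Lncenc1 was at 107 ± 2.78 CPM, while Miat and Rmrp had 0 reads. Their median was 3.16 ± 0.45 (percentile 71.7 among protein-coding lists, or 17.8 among those with at least 1 read), and 4 of 11 tested genes (Gas5, Meg3, Snhg3 and Snhg1) differed between libraries, all lowest in replicate 3 (5 adjusted over the list alone).

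Housekeeping genes had the highest mean median of the 18 lists, 8.81 ± 1.01, and the widest SD between libraries. In replicate 3 their median was 7.65, below those of naive pluripotency (8.57), Polycomb (7.98), general pluripotency (7.83) and cell cycle genes (7.70). Without replicate 1 the naive list was higher (8.53 against 8.48). Hsp90ab1 was at 3197 ± 125 CPM, Eef2 at 2577 ± 58.1 CPM and B2m lowest at 6.34 ± 0.335 CPM. Rplp0 was at 1416 and 1170.4 CPM in replicates 1 and 2 and at 79.4 CPM in replicate 3, and Ppia at 565, 463 and 23.3 CPM. Over all tested genes 6 of 14 differed between libraries, and 7 did adjusted over the list alone. Rplp0, Ppia and Gapdh (22.0 ± 4.64 CPM) have near-identical copies in the annotation that hold reads, so their levels are uncertain. In all, 8 of the 18 lists lay above the 97.5th percentile.

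**Figure D1:**
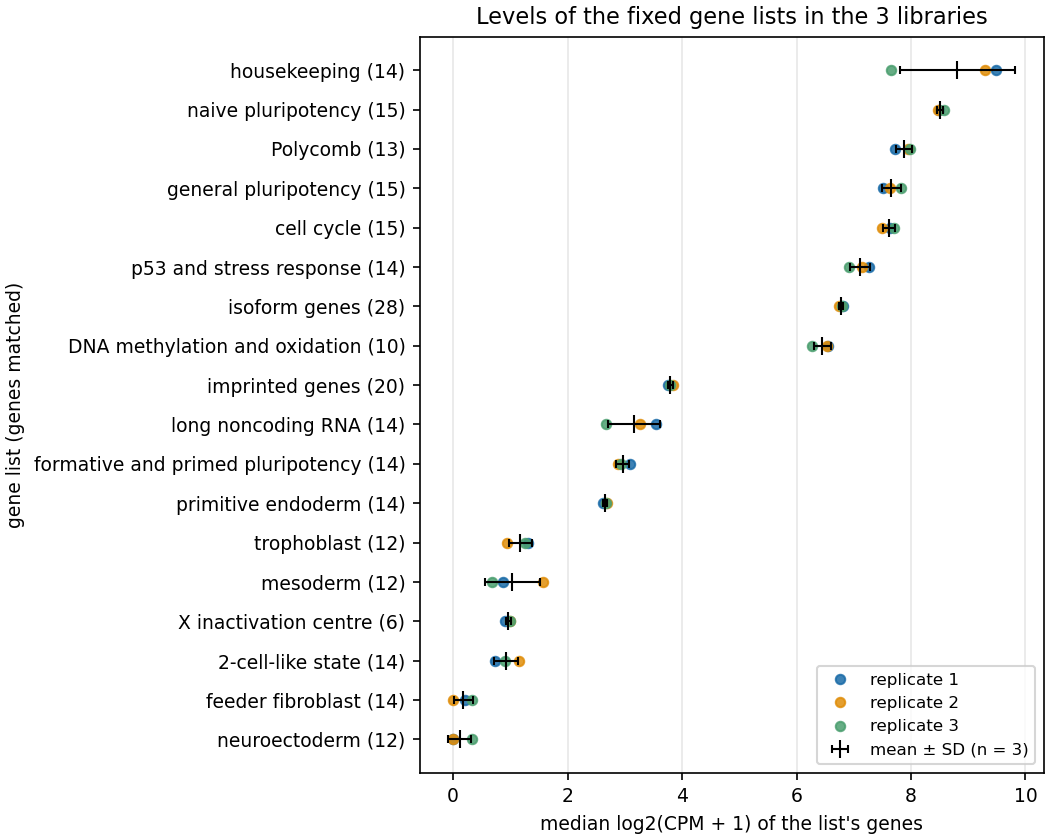
Median log2(CPM + 1) of each gene list (horizontal axis) in replicates 1 to 3 (coloured points), with the mean and SD over the 3 libraries in black. Naive pluripotency lies at 8.51 ± 0.05 and neuroectoderm at 0.11 ± 0.19, and the housekeeping list has its replicate 3 point apart at 7.65.

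The 20 genes of highest mean level were led by Pkm. This gene, which encodes pyruvate kinase (chromosome 9, 59656368 to 59679375), was at 4579 ± 390.0 CPM, followed by Hsp90aa1 at 3781 ± 139.8 CPM, the glucose transporter gene Slc2a3 at 3561 ± 249 CPM, and Dppa5a. Hsp90ab1, Set (2679.9 ± 47.4 CPM), Eef2, Ubb (2545 ± 58.3 CPM), Aldoa (2395 ± 185 CPM), Eif4g2 (2161 ± 269.9 CPM), Rpl4 (2159.6 ± 199.6 CPM) and Eef1a1 (2082 ± 89.8 CPM) also stood among the first 20. So did the RNA-binding protein genes Hnrnpa1 (2043 ± 69.97 CPM), G3bp1 (2029 ± 132 CPM) and Hnrnpu (1947 ± 128 CPM), and the tubulin gene Tubb5 (1906 ± 65.5 CPM). The remaining 4 are annotated copies of other abundant genes, and their counts are uncertain. These were Ftl1-ps1 (3242 ± 506 CPM), Rpl3-ps1 (2894 ± 247 CPM), Eno1b (2446 ± 209 CPM) and Gm15459 (1906 ± 2279.6 CPM), near-identical to Ftl1, Rpl3, Eno1 and Hspa8.

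Among reads assigned to known transcripts, most genes used mainly 1 isoform. Apart from the exons of Pkm, the shares here leave out reads of all other classes, and known models took 72.0 ± 2.26% of reads. Pkm was read almost wholly as its M2 form. Exon 10, which marks M2 (chromosome 9, 59675568 to 59675734), was in 99.1 ± 0.0671% of the reads holding exon 9 or 10 (n = 3), and the M1 exon 9 in 0.938 ± 0.0671%. The transcript Nanog-201 held 99.6 ± 0.209% of known-transcript reads of its gene, Sall4-201 held 96.0 ± 0.695%, Srsf3-202 held 94.7 ± 0.280% and Mta1-205 held 91.8 ± 2.80%, while Pou5f1-201, Esrrb-206 and Tpm3-201 held 100%. Other listed genes were split. The most read transcript held 71.6 ± 1.72% in Zfp207, 66.3 ± 7.78% in Mbd2, 62.0 ± 6.41% in Tcf7l1, 61.3 ± 0.232% in the splicing regulator Ptbp1, 57.4 ± 2.30% in Tpm1, 50.3 ± 6.15% in Ptbp2, 49.8 ± 2.15% in Srsf7, 41.9 ± 0.957% in Hnrnpd, 31.7 ± 3.58% in Dnmt3b and 28.9 ± 0.428% in Tcf3. Clk1, Dnmt3l, Esrp1, Foxp1, Grhl2, Mbnl1, Mbnl2, Numb, Rbfox2 and Tpm2 had fewer than 30 known-transcript reads in at least 1 library, too few for a share.

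Across the 6068 genes with at least 30 known-transcript reads in every library, 1161 (19.1%) had at least 2 isoforms at or above 10% in every library, and the same isoform was the most read in every library in 5950 (98.1%). Usage differed between libraries in 18 of 1929 tested genes by the chi-square test with Benjamini-Hochberg adjustment, and 178 passed an unadjusted threshold of 0.05. In the genes given here from the 10 with the widest ranges, the share was lowest in replicate 3. Rpl10a-201 held 82.3% and 84.5% of known reads in replicates 1 and 2 and 10.5% in replicate 3, and Rps2-208 held 72.1%, 72.4% and 19.2%. Gps1-202, Rpl31-201, Rpl28-201, Rps27a-202, Morf4l1-202, Rpl37a-204 and Hnrnpa3-203 had ranges from 49.7 to 14.7 percentage points. Without replicate 3, 1 gene of 2309 differed, and among the 1708 genes with no near-identical copy 4 did. With in catalog and not in catalog models counted too, usage differed in 141 of 5620 genes. With them, 1877 of 6738 genes (27.9%) had at least 2 isoforms at or above 10% in every library.

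Known transcripts held most reads, but models outside the annotation were far more numerous. Known models took 72.0 ± 2.26% of reads (n = 3) and 10.2 ± 1.53% of models. Incomplete splice matches took 8.59 ± 0.133% of reads, in catalog models 7.21 ± 0.241% and not in catalog models 4.64 ± 0.355%, each between 24.1% and 28.3% of models. Genomic, intergenic and antisense models took 3.04 ± 0.716%, 2.33 ± 1.06% and 2.20 ± 0.936% of reads, and each was lowest in replicate 3 (2.24%, 1.14% and 1.12%). The known share exceeded that of incomplete splice matches by 63.4 ± 2.34 percentage points, and in catalog exceeded not in catalog by 2.57 ± 0.146 points, in 3 of 3 libraries (each exact sign-flip p = 0.25, the smallest this design allows). Incomplete splice matches exceeded in catalog models by 1.38 ± 0.357 points (exact sign-flip p = 0.25), but by 0.511 points in models of 5 or more reads and 0.705 points in multi-exon models. The not in catalog share was 1.91% in models of 5 or more reads. Antisense minus intergenic reads came to -0.134 ± 0.158 points, of the same sign in 3 of 3 libraries (exact sign-flip p = 0.25) but with a mean smaller than its SD, and intergenic minus antisense was -0.0388 in multi-exon models.

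**Figure D2:**
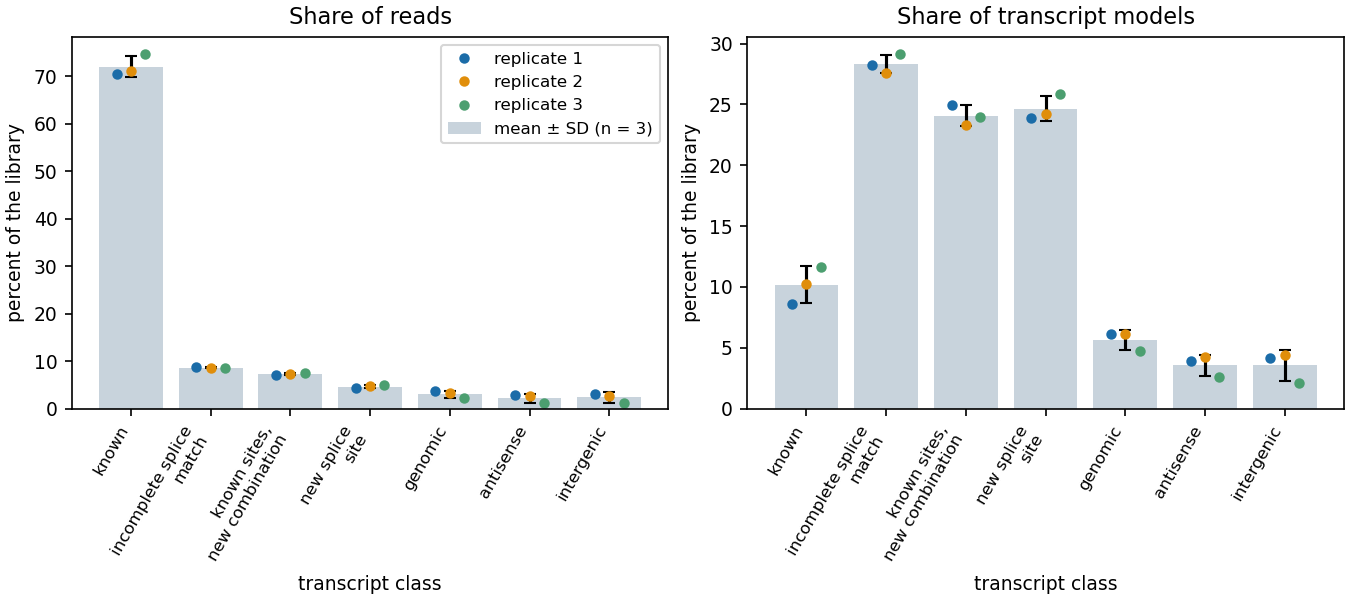
Percent of reads (left) and of transcript models (right) in each transcript class, with bars for the mean and SD over the 3 libraries and points for each replicate. Known models hold 72.0% of reads and 10.2% of models, and the genomic, antisense and intergenic shares of reads are lowest in replicate 3.

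Several abundant genes were read mainly through a chain of introns outside the annotation. In Cct6a, a subunit of a cytosolic chaperonin, a not in catalog model (chromosome 5, 129786998 to 129846371) at 640.4 ± 60.3 CPM held 85.2 ± 0.746% of the gene's reads (n = 3), with 1 unannotated intron from 129794561 to 129844936. In catalog models held 93.0 ± 1.20% of the reads of Phb2 (285 ± 29.9 CPM), 91.4 ± 1.18% of Oaz1 (213 ± 144 CPM), 89.3 ± 0.575% of Sept7 (213 ± 25.3 CPM), 40.8 ± 2.13% of Slc29a1 (229.6 ± 25.8 CPM) and 39.3 ± 1.22% of the Polycomb gene Mtf2 (205 ± 24.8 CPM). A pair of Hnrnpk models shared an unannotated intron (chromosome 13, 58393775 to 58394059) and held 35.9 ± 1.36% and 26.4 ± 1.02% of its reads. A model of Ewsr1 held 25.9 ± 1.17% and a model of Pitpnb 74.8 ± 1.13%. Oaz1 had 955, 554 and 82 reads on its model, lowest in replicate 3. Of 266947 multi-exon chains classed as in catalog or not in catalog, 23253 (8.71%, 95% Wilson interval 8.60 to 8.82%) were found in every library, and these held 58.7% of the reads of such chains. The interval treats chains as independent and leaves out depth and differences between libraries. Matched within its own class, the share was 9.70% for in catalog and 3.80% for not in catalog chains. It was 62.3% for known transcripts and 19.1% for incomplete splice matches. Some identical chains carried both the in catalog and the not in catalog class, among them the Hnrnpk pair and the Pitpnb model. Within class, 12587 in catalog and 5599 not in catalog chains were found in every library, against 23253 when class was ignored. The shares of these classes thus leave out chains whose class differed between libraries, and the difference between the shares is uncertain. At a minimum of 5 reads per library, 34.5% of chains of either class were found in every library.

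Reads fell in 18051, 17036 and 15719 annotated genes in replicates 1, 2 and 3, in the order of their depth. In all, 14296 of 19889 genes with any read were found in every library, 12827 of them protein-coding. After thinning to the depth of the smallest library the numbers were 16554, 16544 and 15719, lowest in replicate 3. With known transcripts alone the thinned numbers were 13162, 13160 and 13009, and with all classes at a minimum of 5 reads they were 12197, 12135 and 11775, again lowest in replicate 3. With both choices together they were 9962, 9952 and 9957, and 8706, 8666 and 8696 at a minimum of 10 reads, where replicate 3 was not lowest.

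Replicate 3 differed from the other libraries in a set of genes that included nearly all ribosomal protein genes, a group chosen after the values were seen. Whether this library was aligned and assigned in the same way as the others is not given in the sources used here. It was not tested over all genes. At the locus of Gm15459, the part of the reads assigned to the gene differed between libraries. The gene held 420, 2226 and 7506 reads in replicates 1, 2 and 3, and all models overlapping it held 12164, 8404 and 7506. Replicate 3 also had fewer reads in unannotated genes, 2.56% against 6.33% and 5.67%. The ribosomal protein genes' summed level was 25363 CPM in replicate 1, 22294 CPM in replicate 2 and 9311 CPM in replicate 3. Together with their near-identical copies, a sum also chosen after the values were seen, it was 40677, 33475 and 24301 CPM, and 40803, 33486 and 24448 CPM with unannotated models on the same strand over these genes. The copies alone stood at 15314, 11181 and 14990 CPM. Of 79 tested ribosomal protein genes, 76 (96.2%) differed between libraries and were lowest in replicate 3, against 1115 of 11872 other genes (9.39%). These sets were not matched for transcript length. In genes of at least 20 CPM with no copy, the median log2 ratio of replicate 3 to the others was -0.393 under 500 bases. It was -0.325 at 500 to 1500 bases and 0.0606 over 1500 bases. Over all genes, 2391 of 11951 (20.0%) differed between libraries by more than counting error, 1191 of them lowest in replicate 3 and 772 lowest in replicate 1, while 1234 were highest in replicate 1 and 713 highest in replicate 3. In 459 of them replicate 3 lay more than 2 times below both others, against 26 in replicate 1 and 58 in replicate 2. Without replicate 1 the count was 945, without replicate 2 it was 2235 and without replicate 3 it was 1067. Among the 10515 genes with no near-identical copy it was 1609 (15.3%). The 10 genes of widest relative spread included Gm48855, Dqx1, Gm15459, Gm10052, BC002059, Gm2423, Clca4a, Rps29 and Gm10259. Gm48855 had 0, 551 and 0 reads, Dqx1 had 5, 408 and 1, Rps29 had 470, 389 and 4, and Gm15459 had 420, 2226 and 7506. The most read model assigned to Gm48855 spans 32 bases of chromosome 9 (64279983 to 64280014), outside the annotated gene (64228339 to 64230795). That of BC002059 (chromosome 17, 17179261 to 17206224) also lies outside its gene (16951539 to 16974157). The genes Gm15459, Gm10052, Gm2423 and Gm10259 have near-identical copies that hold reads, so their counts are uncertain.

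**Figure D3:**
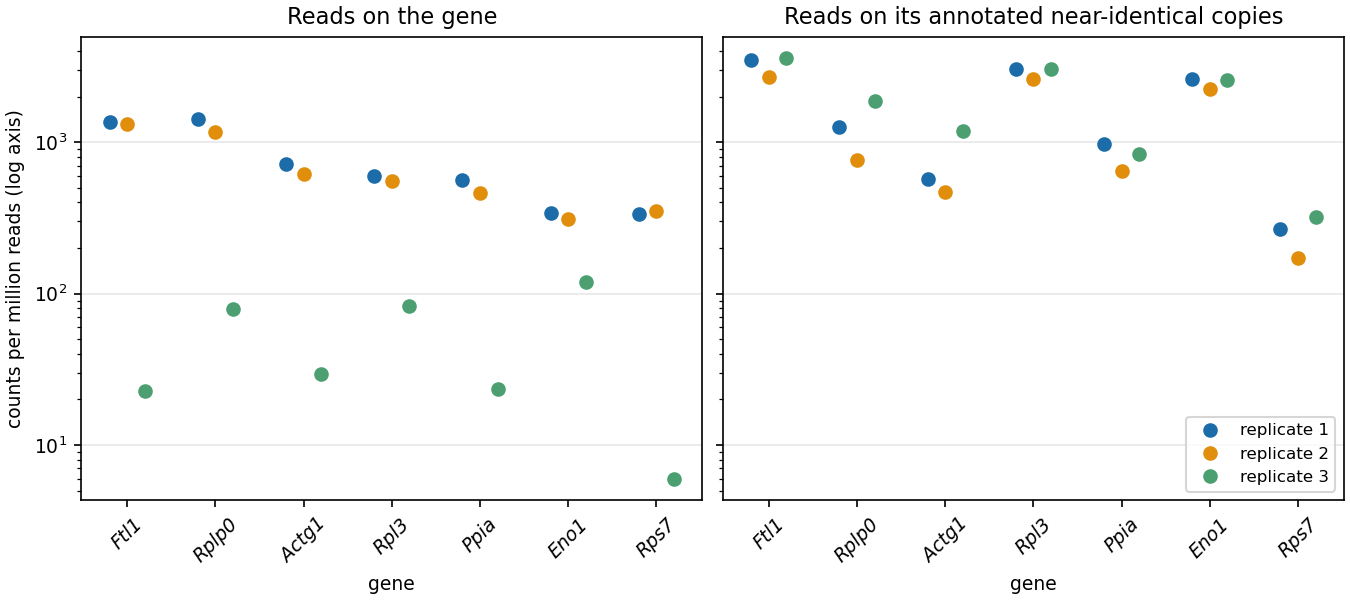
Levels in CPM (log axis) of 7 abundant genes low in replicate 3 (left), chosen after their values were seen, and of their annotated near-identical copies (right), 1 point per library. In replicate 3 Rplp0 stands at 79.4 CPM and its copies at 1861 CPM, and Actg1 at 29.2 CPM and its copies at 1180.2 CPM.

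The libraries resembled each other in most genes. The common biological coefficient of variation was 0.171 over 10218 genes by edgeR, and it was 0.113 without replicate 3. Pearson's r of log2(CPM + 1) across 19889 genes was 0.980 for replicates 1 and 2 and 0.967 for each pair with replicate 3, with Spearman's rho of 0.958, 0.943 and 0.943. The median coefficient of variation among the 4645 genes at a mean of 50 CPM or more was 9.41%, and 7.99% without replicate 3.

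Reads that matched only part of a known transcript were more frequent in genes with long transcripts. Incomplete splice matches made up 2.12 ± 0.528% of reads in genes with a longest transcript under 1 kb, 7.07 ± 0.607% at 2 to 3 kb and 18.4 ± 0.916% at 4 kb and over (n = 3). The difference between the outer groups was 16.3 ± 0.574 percentage points, in the same direction in 3 of 3 libraries (exact sign-flip p = 0.25, the smallest possible). Across 10817 genes, Spearman's rho between length and this share was 0.507. Of the incomplete reads, 77.7 ± 1.28% were suffixes, which keep the 3' end of the transcript. Replicate 3 held fewer short models, with 1.43% of reads in models under 300 bases against 5.56% and 5.02%, and a median model length per read of 2792 bases against 2473 and 2663.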

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

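The prediction that genes low in replicate 3 often have near-identical copies was written before the result was seen, and the wider definition of a copy and all other tests in this part were chosen after it. Of 31801 loci not assigned to an annotated gene, some of which overlap one, 1207 had more reads than a count of 0 allows in every library. The 5 with most reads are singled out here. The first lies on chromosome 17 from 39843013 to 39848827 on the minus strand, at 1294 ± 372 RPM (reads scaled to the library total, n = 3), and overlaps Gm26917 and Gm42418 on the other strand and AY036118 and CT010467.1 on its own. The second lies on chromosome 15 from 22699651 to 22705006 on the minus strand, opposite Cdh18, at 931 ± 45.7 RPM. A locus on chromosome 11 (57542916 to 57560261, minus strand) stood at 893 ± 74.2, another on chromosome X (117315376 to 117322029, minus strand) at 863 ± 32.5 and a further locus on chromosome 13 (113718464 to 113723843, plus strand) at 678 ± 94.5 RPM. None of the last 3 overlaps an annotated gene of GENCODE M21 (0 genes), though the authors' classes for the locus on chromosome 13 were antisense and intergenic. No explanation was tested for any of the 5.

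Of the genes with a mean of at least 20 CPM, 235 differed between libraries and had replicate 3 more than 2 times below both others, with a median transcript length of 886 bases against 2968 for other genes. Loss of short transcripts was examined in the 99 genes whose copies are no longer than the gene and hold at least 20 reads. The median log2 ratio of replicate 3 to the others was 0.335 on these copies and -2.32 on these genes. It was higher on the copies by a median of 2.74 (95% bootstrap interval 2.46 to 3.00, in 98 of 99 genes), and by the same median (2.47 to 2.97) with unannotated models over the copies counted. The genes were chosen for a low level in replicate 3 and the copies were not. Copies that had not changed would also give a wide gap, so the gap and the 98 of 99 genes cannot decide the question. The copies themselves, no longer than the genes, did not fall as a set (median 0.335). The intervals in this part resample genes, some of which share copies, and do not cover the spread between libraries. For the set as a whole loss of short transcripts stays open, since at 500 to 1500 bases genes with a copy lay only -0.23 (-0.31 to -0.12) from genes without one, short of the bound of -0.5 set for excluding it. Reads shared with copies may contribute but are not settled: under the narrower definition the pattern's genes had a copy 0.911 times as often as other genes of like length (0.691 to 1.19), which lies under the bound of 1.5 set in advance for arguing against it, and under the wider one 1.64 times (1.38 to 1.95), but the narrower one gave no copy for Rplp0, whose copies held 1253, 763 and 1861 CPM. A lower level of these RNAs in that culture also stays open, as the main transcript differed from the other models of the same gene by -0.34 (-0.63 to -0.09), and in pattern genes with a copy the median log2 ratio was -2.02 for the gene, 0.25 for copies holding at least 20 reads and -0.86 (-0.95 to -0.75) for their sum, or -0.81 with unannotated models added, which unchanged copies would raise in any case.

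For the 10 genes of widest relative spread, the explanation tested was reads of one locus assigned to different models or strands in different libraries. All reads overlapping the most read model of each gene, on either strand, were summed. For Gm48855 and BC002059 this model lies outside the annotated gene. In Gm15459 (from 121.2% to 8.31%) and BC002059 (from 107% to 11.4%) the sum brought the coefficient of variation to less than 0.5 times the gene's own. These are 2 of the 10, fewer than most of the set. For BC002059 the sum left out reads of the gene itself, with 118 reads in the sum against 194 on the gene in replicate 3. Its lower coefficient therefore cannot bear on this explanation. In 3 more, Gm48855, Dqx1 and Gm10052, the coefficient came close to that bound (0.501, 0.507 and 0.515 times). The bound was set after the values were seen, so the explanation stays open for the set. In the other 5, among them Gm2423, Clca4a, Rps29 and Gm10259, the sum left the coefficient at 0.982 times or more, and no biological explanation was tested for any of the 10.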

How the results depend on the processing

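Genes with no near-identical copy, and genes with at least 10 counts for the correlation, were alternatives chosen after seeing the data. No paired analysis between groups was possible because there is 1 group, while differences within a library were paired by library. Of 267 values recomputed under an alternative, 205 stayed within a margin, 61 moved beyond it and 1 changed sign. The margin was 1.5 times for counts, the Wilson interval for shared chains and the SD between libraries for most other values. For the coefficient of variation it was the SD of the values with 1 library left out, and for Pearson's r the SD over pairs of libraries. The value that changed sign was intergenic minus antisense reads, 0.134 ± 0.158, which was -0.0388 in multi-exon models, an alternative that leaves out single-exon models. List levels near 0 turn negative with a pseudocount of 0.1 CPM by construction (5 lists), and by a choice made once signs had been seen these are not counted as changes of sign. The count of lists above the 97.5th percentile was 8 under every alternative run.

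The common biological coefficient of variation ranged from 0.113 to 0.217 when 1 library was left out. The square root of the median gene-wise dispersion of DESeq2, which is on the scale of such a coefficient, lay at its floor of 1e-04. Mean pairwise Pearson's r was 0.922 with a pseudocount of 0.1 CPM, 0.981 with 5 CPM, 0.954 for genes with 10 or more counts and 0.967 to 0.980 with 1 library left out. Genes differing between libraries numbered 945 to 2235 with 1 library left out. A minimum of 10 reads gave 11161 genes, minimums of 5 and 10 reads gave 36318 and 20766 models, and known transcripts alone gave 23670 models. The known share of reads was 81.2% in models of 5 or more reads and 77.1% in multi-exon models. Chains shared by every library made up 10.4% with splice sites within 5 bases, 21.2% and 34.5% at 2 and 5 reads, and 17.2 to 18.03% over pairs of libraries. Isoform usage differed in 141 genes with in catalog and not in catalog models, 4 without near-identical copies, and 1 to 17 with 1 library left out. Genes with at least 2 isoforms numbered 1877 with those models, 546 at 100 reads and 708 at a share of 20%. The excess of incomplete reads in long genes was 15.6 points by the length of the most read transcript. Apart from alternatives that change what is counted, the cause was not tested.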

Other observations

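The tests in this part were chosen after the result was seen, except that on Gapdh, and the gene groups in it were chosen after their values were seen. Genes of glucose uptake and glycolysis summed to 15340 ± 357 CPM over 16 genes (n = 3). Pkm and Slc2a3 led them, with Aldoa at 2395 ± 185 CPM and Ldha at 1328 ± 66.9 CPM, and the hexokinase genes Hk2 and Hk1 were at 296 ± 23.7 and 225 ± 21.6 CPM. By the homogeneity test 10 of the 16 differed between libraries, of which Pgam1 (604, 572 and 178 CPM), Eno1 (338, 309 and 119 CPM), Aldoa (2609, 2292 and 2285 CPM) and Tpi1 (235, 189.5 and 184 CPM) were lowest in replicate 3. Slc2a3, Hk1, Pfkl, Pfkp and Pkm were lowest in replicate 1, and Ldha in replicate 2. With its copies added Eno1 stood at 2942, 2566 and 2712 CPM, not lowest in replicate 3. Pgam1 with its copies stood at 709.7, 779.9 and 254 CPM, but at 910.3, 846 and 883 CPM once unannotated models on the same strand over these genes were counted too. A set of 12 chaperone genes summed to 14726 ± 561 CPM, with the mitochondrial Hspa9 at 1757 ± 194 CPM, Hspd1 at 1527 ± 90.9 CPM and the chaperonin subunit Cct5 at 1041 ± 51.8 CPM. Of these 12, 10 differed between libraries, and Hspa8 and Hspe1 were lowest in replicate 3 (54.3 and 88.3 CPM). Hsp90aa1, Hsp90ab1, Hspa9 and Cct6a were lowest in replicate 1, and Hspa5, Hspd1, Cct2 and Cct5 in replicate 2. With its copies added Hspa8 was highest in replicate 3 (291, 1255 and 4533 CPM), but unannotated models over these genes held 11744, 6178 and 0 reads, and with them the sums were 4178, 4305 and 4533 CPM. Eno1, Pgam1 and Hspa8 have near-identical copies, so their counts are uncertain.

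The 13 mitochondrially encoded protein genes summed to 5914 ± 1108 CPM. Within them mt-Cytb was at 1728 ± 336 CPM, mt-Co1 at 1325 ± 243 CPM and mt-Nd1 at 1005 ± 166 CPM, while mt-Nd6 was at 0.893 ± 0.360 CPM and mt-Atp8 at 1.37 ± 1.26 CPM. All 9 that could be tested differed between libraries, and the sum was 7193 CPM in replicate 1 against 5311 and 5237 CPM in replicates 2 and 3. Host genes of small nucleolar RNAs summed to 338, 297 and 132 CPM over 8 genes, and 4 of the 7 tested differed between libraries. In this group Snhg3 was at 52.3, 36.5 and 5.97 CPM and Snhg5 at 59.9, 42.0 and 24.5 CPM.

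Gapdh, a glycolytic enzyme gene usually among the most abundant, had 77, 48 and 28 reads, while 17 annotated near-identical copies of it held 3713, 2148 and 1668 reads. That reads of Gapdh were assigned to its copies is a candidate explanation, and the copies held at least 44.75 times as many reads as Gapdh in each library. With the narrower definition of a copy, 3 copies held at least 13.3 times as many. Gm7336 held more of these reads than any other copy (1309, 635 and 822). The order of the next copies differed between libraries, with Gm12671 at 843, 508 and 151, Gm5559 at 690, 386 and 196 and Gm13394 at 129, 240 and 316 reads. Expression of the copies themselves was not tested, and no biological explanation was tested.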
